A study of Mus musculus with 12 samples.

How the data were processed

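Total RNA from mouse embryonic lungs at day 14.5 was profiled on single-channel Affymetrix arrays with a biotin label. The 12 arrays fall into 3 genotypes of 4 specimens each. The controls carried the Shh-Cre allele alone, the Yy1 mutants carried the same allele with both Yy1 copies floxed, and the Dicer mutants carried it with both Dicer copies floxed. Per the labels, RNA was taken up in Trizol, treated with DNase and cleaned on RNeasy columns. The labels give no litter, batch, scan date or sex, and they do not say whether a specimen held 1 embryo or several.

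The deposited values are on a log2 scale and had been normalised between arrays by the authors. The summary method, the normalisation method, the software and the array design are not given in the sources used here, and base 2 is inferred from the values, which ran from 1.10 to 13.6. The 12 array medians lay between 5.99 and 6.08. Pairs of arrays correlated at 0.978 to 0.991 across probe sets, and 0 pairs were identical. All columns of the table were mapped to a specimen. The number of arrays, 4 per genotype, limits the precision of every value.

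The table held 41345 probe sets, of which the platform annotation listed 25335. Of these, 23521 were paired with exactly 1 gene symbol and 1814 with several. The other 16010 probe sets had no listed gene. Only probe sets with 1 symbol were used, and 23328 of them matched a mouse RefSeq gene (GRCm38.p6 annotation, used only for names and for which genes neighbour each other) by Entrez identifier, with 0 symbols changed. Where a gene had more than 1 probe set, which applied to 1082 genes, the probe set with the highest mean over all 12 arrays stood for it. This left 22180 genes. No filter on dim probe sets and no further normalisation was applied. The build of the array is not named, so no positions are given.

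The genotypes were compared with limma 3.58.1 in R 4.3.3. The 3 genotypes were fitted in one linear model with 9 residual degrees of freedom, followed by empirical Bayes moderation of the variances, and each mutant was compared with the control and the mutants with each other. The test was two-sided. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05 over all genes of a comparison. Differences are log2 fold changes with their standard error (SE) from the model, and levels are log2 means with the standard deviation (SD) over 4 arrays. Tables were prepared with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots were drawn with matplotlib 3.10.9.

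The gene lists, the tests, the rule for named genes and most alternatives were fixed before the data were examined. The 36 lists cover lung cell types, other cell types a lung specimen could hold, signalling pathways and cell processes. Of their 580 entries, 535 were measured. Each list was tested against all other genes with camera, limma's competitive list test, at its preset correlation of 0.01, adjusted over the 36 lists. The same test with the correlation estimated from the data was the alternative. With an estimate, camera also uses the 9 residual degrees of freedom of the arrays, where the preset uses the number of genes. List members past the gene test were counted over all genes tested and also with the adjustment over the list alone. Named genes are the targeted genes, 14 genes of lung branching, the 10 largest changes each way per mutant (5 between the mutants) among called genes whose groups did not overlap, and up to 4 members with the smallest p of each list that passed its test or had at least 3 called members. Predicted genes, Riken clones and sex-linked control genes were kept out of the largest changes.

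The mutants share their controls, so shared calls and the correlation of the effects across genes were set beside 100 simulations of unchanged groups measured against the same controls, beside the overlap of independent lists, and beside a comparison in which each mutant was set against a different pair of controls, in all 6 orders. The fit was tested on simulated normal values that had the mean and the residual spread of each measured gene, in which randomly drawn genes were shifted. A shift of 0.5 on the log2 scale was called for 62.7% of 67 genes in the Yy1 comparison and 71.6% of 67 in the Dicer comparison, a shift of 1 for 97.0% and 94.0%, and a shift of 2 for 100% in both. There were 9 and 8 false calls.

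The alternatives were quantile normalisation, equal array medians, removal of the dimmest 30% of genes, the mean of all probe sets of a gene, an intensity trend with a robust prior, a fit of only the groups compared, array weights, a minimum change of 1.5-fold, the replicate number as a block, each array left out in turn, and controls split between the mutants. A covariate of Xist minus Eif2s3y for the sex of the specimens and the removal of 3 arrays with raised Y-linked genes were added after the values were seen. Probe sets with no listed gene or with several symbols were left out because no single gene could be assigned to them.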

Results

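Gene expression was measured in whole lungs of mouse embryos at E14.5, a stage at which the airways are branching. The Shh-Cre allele is one that targets the lung epithelium, and the same RNA also contains mesenchyme, vessels and blood cells. In which cells the floxed gene was lost was not measured. Each of the 3 genotypes, control, Yy1 mutant and Dicer mutant, was represented by 4 arrays, and the controls carried the Cre allele as well. The array medians differed by little, from 5.99 in control 1 to 6.08 in Yy1 mutant 3. On 3 mutant arrays the Y-linked genes Eif2s3y, Kdm5d and Uty stood above the other arrays. Eif2s3y read 7.99 in Yy1 mutant 2, 7.84 in Dicer mutant 4 and 5.92 in Yy1 mutant 3, against 3.73 to 4.48 in the 4 controls, so the number of called genes in each comparison and the number of shared calls are given without these 3 arrays as well. The p-values of the gene test measure only the spread between these specimens. Those of the list test with the preset correlation set the members of a list against all other genes. They rest on the spread across genes under an assumed correlation of 0.01, not on the number of specimens.

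Yy1, a zinc finger transcription factor, was measured by 1 probe set. Its level was 9.03 ± 0.0710 in controls and 8.84 ± 0.104 in Yy1 mutants (SD, n = 4). The difference of -0.19 (SE 0.0680) between Yy1 mutant and control lungs did not pass the test (adjusted p = 0.125, and 0.0598 to 0.552 over the alternatives), and Dicer mutants differed by -0.03 (adjusted p = 0.847). Dicer1, which encodes the enzyme that cuts microRNA precursors, was also measured by 1 probe set, at 8.81 ± 0.165 in controls, 8.67 ± 0.134 in Yy1 mutants and 8.19 ± 0.115 in Dicer mutants. It fell in Dicer mutant lungs by 0.61 (SE 0.0953) on the log2 scale (adjusted p = 0.00127) and differed by -0.14 in Yy1 mutants (adjusted p = 0.477). Where these probe sets lie relative to the floxed exons is not known, and whole lung RNA includes cells without Cre.

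**Figure D1:**
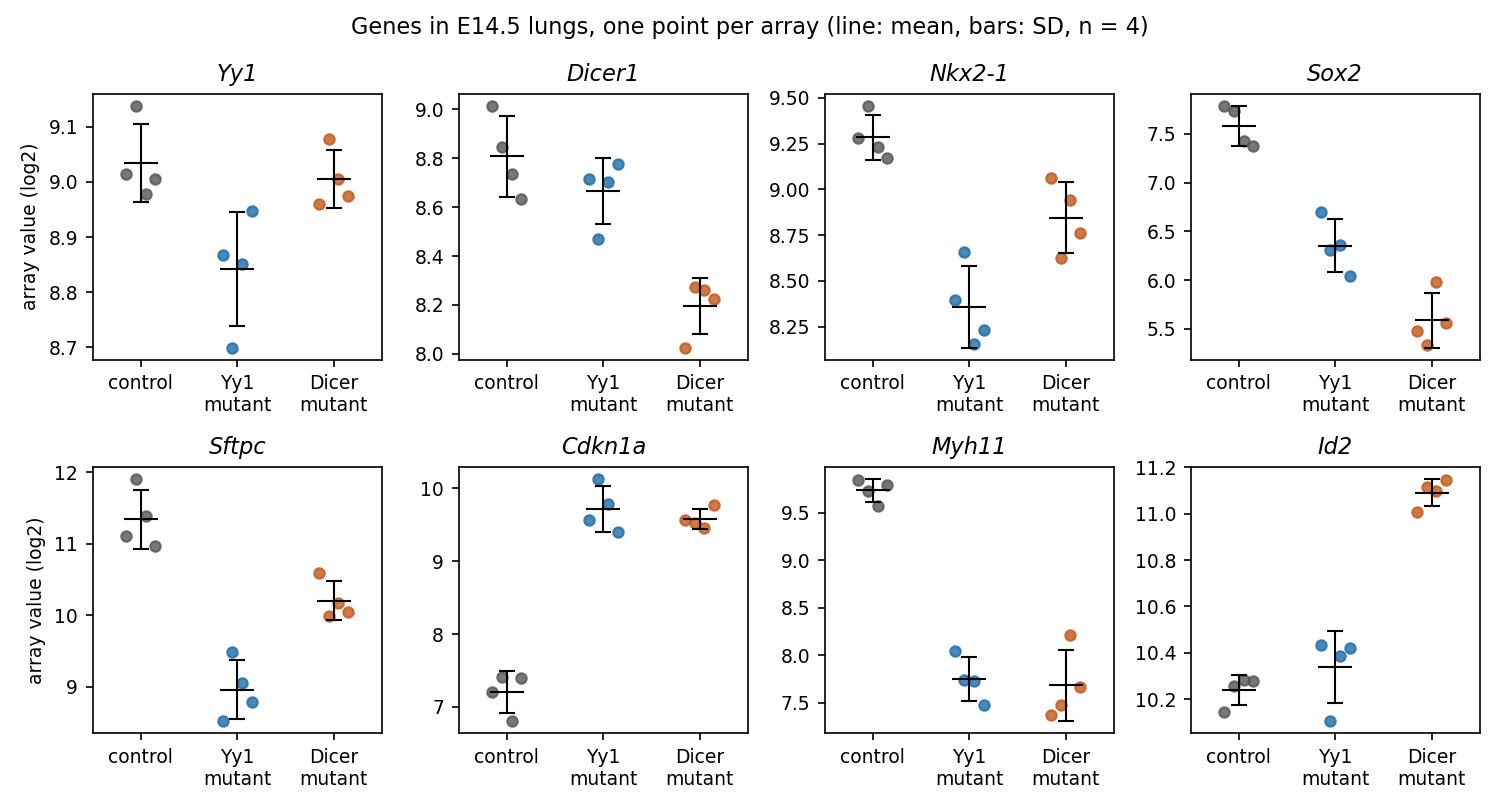
Log2 array values of 8 genes in control, Yy1 mutant and Dicer mutant lungs, with 1 point per array, the mean as a line and the SD as bars (n = 4). Dicer1 was lower in all 4 Dicer mutant arrays than in any control, Cdkn1a was higher in all 8 mutant arrays than in any control, and Id2 was higher in the 4 Dicer mutant arrays than in all others.

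The comparison of Yy1 mutant with control lungs concerns the floxed Yy1 alleles under a Cre allele that targets the lung epithelium. Branching itself was not measured. Markers of the epithelium, the proximal airway and smooth muscle were lower in the mutants, while p53 targets, macrophage markers and mesenchymal markers were higher. Of these lists, the epithelial one lost its call with an estimated correlation (adjusted p = 0.13). Aldh1a7, an aldehyde dehydrogenase, fell 10.8-fold from 10.31 ± 0.122 to 6.88 ± 0.228 (SD, n = 4; adjusted p = 5.1e-08). The membrane mucin Muc1 fell 8.04-fold and Sftpc, the surfactant protein C gene that marks distal lung epithelium early, fell 5.21-fold from 11.34 ± 0.414 to 8.96 ± 0.411. Cdkn1a, the cyclin-dependent kinase inhibitor p21, rose 5.71-fold to 9.72 ± 0.314 (adjusted p = 9.56e-07). In all, 1465 of 22180 genes were called, 614 higher and 851 lower, of which 33 and 63 changed at least 2-fold.

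Of 25 measured pan-epithelial markers, 15 fell and 10 were not called. Adjusted over the list alone, 18 fell. The list test gave adjusted p = 5.64e-17 with a median of -0.42, and adjusted p = 0.13 with an estimated correlation. Foxa2, a forkhead factor of foregut endoderm, fell by 0.96, Esrp2, an epithelial splicing regulator, by 0.87, the transcription factor Elf5 by 1.19 and the tight junction gene Cldn6 by 0.93. Nkx2-1, which specifies lung epithelium, fell by 0.93 (SE 0.118), from 9.29 ± 0.124 to 8.36 ± 0.223. Of 13 proximal airway markers, 5 fell (7 adjusted over the list alone) and 8 were not called, with a median of -0.22, adjusted p = 2.9e-07 and adjusted p = 0.01 with an estimated correlation. Sox2, the transcription factor of the conducting airway, fell by 1.23 (SE 0.156). The cholecystokinin receptor Cckar fell by 2.59 and Aldh1a1, a retinaldehyde dehydrogenase, by 1.69.

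Distal tip progenitor markers, which label the growing ends of the airways, went both ways. Of 14, 8 fell, 2 rose and 4 were not called. Adjusted over the list alone, 8 fell and 3 rose. The median was -0.44 (adjusted p = 0.00167, and adjusted p = 0.169 with an estimated correlation). Etv5, a transcription factor induced by Fgf signalling, fell by 1.17, or by 0.68 when all its probe sets were averaged. Fgfr2, the epithelial receptor for Fgf10, fell by 0.84, Mycn by 0.72 and Wnt7b by 0.55. Sox9 fell by 0.42 (adjusted p = 0.0103) and Shh, the ligand gene at the locus of the Cre allele, by 0.47 (adjusted p = 0.00778). Without the 3 arrays with raised Y-linked genes, their adjusted p was 0.12 and 0.0779. Gata6 rose by 0.41 and Etv4 by 0.49, named after their values were seen. Bmp4 differed by 0.29 (adjusted p = 0.0641), and passed the test in 5 of 22 alternatives. These were the fits without control 2 (adjusted p = 0.0432) or Yy1 mutant 4 (0.0438), after quantile normalisation (0.0455), without the dimmest genes (0.0342) and with the intensity trend and robust prior (0.0156). Id2 differed by 0.10 (adjusted p = 0.573) and Spry2 by 0.05 (adjusted p = 0.827).

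Markers of smooth muscle, a cell type outside the epithelium, were lower. Of 13, 7 fell (12 adjusted over the list alone) and 6 were not called, with a median of -0.41, adjusted p = 1.65e-12 and adjusted p = 0.037 with an estimated correlation. Myh11, the smooth muscle myosin heavy chain, fell 3.98-fold from 9.74 ± 0.118 to 7.75 ± 0.231. Actg2, a smooth muscle actin, fell by 1.80, Synpo2 by 1.16 and Myocd, the coactivator that drives smooth muscle genes, by 1.69. Lung mesenchyme markers moved the other way. Of 16, 7 rose (9 adjusted over the list alone) and 9 were not called, with a median of 0.25, adjusted p = 3.77e-07 and adjusted p = 0.0384 with an estimated correlation. The growth factor receptor Pdgfra rose by 0.67, the proteoglycans Lum by 1.29 and Dcn by 0.69, and Fgf10, the mesenchymal growth factor that directs bud outgrowth, by 0.88 (SE 0.131).

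Of 20 measured p53 targets and apoptosis genes, 9 rose and 11 were not called. Adjusted over the list alone, 13 rose and 1 fell. The median was 0.39, with adjusted p = 7.86e-13 and adjusted p = 0.01 with an estimated correlation. Besides Cdkn1a, cyclin G1 (Ccng1) rose by 1.36, the ectodysplasin receptor Eda2r by 1.29 and Trp53inp1 by 0.74. Macrophage and leukocyte markers rose as well, 11 of 16 (13 adjusted over the list alone), with a median of 0.42, adjusted p = 1.51e-12 and adjusted p = 0.037 with an estimated correlation. The complement gene C1qb rose by 0.72 and the Fc receptor chain Fcer1g by 0.82. Of 10 cholesterol synthesis genes, 5 fell (9 adjusted over the list alone), with a median of -0.31, adjusted p = 1.64e-08 and adjusted p = 0.037 with an estimated correlation. Squalene epoxidase (Sqle) fell by 0.70 and Insig1 by 0.43. Of 20 cell cycle genes, 5 fell (9 adjusted over the list alone), with a median of -0.16, adjusted p = 1.35e-06 and adjusted p = 0.13 with an estimated correlation. The replication helicase genes Mcm5 and Mcm2 fell by 0.40 and 0.36, and without the 3 arrays with raised Y-linked genes their adjusted p was 0.0932 and 0.103.

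Of 19 basement membrane genes, 6 fell, 1 rose and 12 were not called (10 and 3 adjusted over the list alone), with a median of -0.21, adjusted p = 0.000202 and adjusted p = 0.22 with an estimated correlation. The laminin chains Lama3, Lamb3 and Lama5 fell by 1.04, 0.97 and 0.64, and Frem2 by 0.38. Npnt, an integrin ligand, rose by 0.65 (adjusted p = 0.045) and was named after its value was seen. Of 17 let-7 targets, 3 fell (4 adjusted over the list alone) with a median of -0.04 (adjusted p = 0.0118, and adjusted p = 0.193 with an estimated correlation), and without the 3 arrays with raised Y-linked genes the list gave adjusted p = 0.0774. Its median was -0.08 without control 1, -0.07 without control 2, -0.09 without control 3, -0.14 without control 4, -0.08 without Yy1 mutant 1 and -0.11 without Yy1 mutant 4. Of 11 regulators of epithelial to mesenchymal transition, Zeb1 rose by 0.55 and Fn1 by 0.35 (adjusted p = 0.0837 for Fn1 without the 3 arrays with raised Y-linked genes) while the integrin Itgb6 fell by 0.70. Adjusted over the list alone, 2 rose and 1 fell. The list test gave adjusted p = 0.0185 (median 0.11), adjusted p = 0.193 with an estimated correlation, and adjusted p = 0.115 without control 4. Of 14 cartilage markers, 2 fell, also 2 adjusted over the list alone, with a median of -0.09, adjusted p = 0.0487 and adjusted p = 0.241 with an estimated correlation. Chondromodulin (Cnmd) fell by 1.11. The cartilage call was lost without control 2 (adjusted p = 0.0541), control 4 (0.121), Yy1 mutant 3 (0.089), Yy1 mutant 4 (0.0626) or Dicer mutant 4 (0.0554).

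The Shh, Fgf, Wnt and Bmp lists held called genes in both directions and did not pass the list test. In the Shh pathway list, Hhip, an inhibitor and target of hedgehog signalling, fell 3.88-fold from 9.66 ± 0.127 to 7.70 ± 0.314, and the receptor and target Ptch1 fell by 0.64. The coreceptors Gas1 and Boc rose by 0.58 and 0.41. Of its 14 genes, 3 fell and 3 rose (3 and 4 adjusted over the list alone; list adjusted p = 0.935, median -0.02). Gli1, another target, differed by -0.03 (adjusted p = 0.903) and by 0.00236 without Yy1 mutant 2. Of 17 Fgf pathway genes, 4 rose and 3 fell (6 and 4 adjusted over the list alone; list adjusted p = 0.951). Fgfr3 fell by 0.90. Of 20 Wnt pathway genes, 2 rose and 3 fell (3 and 8 adjusted over the list alone; list adjusted p = 0.0802, median -0.16). The Wnt agonist Rspo2 rose by 0.82 and the Wnt inhibitor Rnf43 fell by 0.68. Of 18 Bmp and Tgf-beta genes, 4 rose and 4 fell (6 and 4 adjusted over the list alone; list adjusted p = 0.935). Bmp7 fell by 0.49 and Ltbp2 by 0.63, while Bambi rose by 0.38.

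Alveolar cell markers did not pass the list test either (adjusted p = 0.0861, median -0.14). Of 16, 5 fell and 4 rose (6 and 4 adjusted over the list alone). Muc1 and Sftpc fell as given, and Pdpn, a marker of type 1 cells, fell by 0.62. Lamp3, a lysosomal gene of type 2 cells, rose by 1.41, from 6.12 ± 0.466 to 7.53 ± 0.147. Among 16 imprinted genes, 2 rose and 1 fell (4 and 1 adjusted over the list alone; list adjusted p = 0.166, median 0.14), and Nnat fell by 0.80. Among 15 stress response genes, 1 rose and 2 fell (3 and 4 adjusted over the list alone; list adjusted p = 0.683, median -0.01), and the serine synthesis gene Psat1 fell by 0.55. Endothelial markers (median 0.09, adjusted p = 0.217), mesothelial markers (0.06, adjusted p = 0.131), Notch pathway genes (-0.07, adjusted p = 0.194) and microRNA biogenesis genes (-0.03, adjusted p = 0.128) did not pass. Nor did neuroendocrine markers (-0.05, adjusted p = 0.511), retinoic acid pathway genes (0.01, adjusted p = 0.662), neural markers (0.02, adjusted p = 0.935), erythroid markers (0.04, adjusted p = 0.935) and heart muscle markers (0.13, adjusted p = 0.935). The remaining lists that did not pass were skeletal muscle (-0.07, adjusted p = 0.454), liver (0.02, adjusted p = 0.475), oesophagus, stomach and thymus (0.05, adjusted p = 0.861), oxidative phosphorylation (-0.02, adjusted p = 0.49), ribosomal proteins (0.07, adjusted p = 0.118), hypoxia response (0.09, adjusted p = 0.558) and sex-linked genes (1.40, adjusted p = 0.473). Median and mean had opposite signs for the Fgf list (0.03 and -0.06, test upwards), the retinoic acid list (mean -0.13, test downwards), the neural list (mean -0.05, test downwards) and the oesophagus, stomach and thymus list (mean -0.01, test upwards), and the Bmp list tested upwards with a median of -0.04 and a mean of -0.00314.

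Other genes with large changes included Tinag, a basement membrane protein gene, which fell 8.34-fold, the gastric protease gene Cym, which fell 6.79-fold, and the chloride channel gene Cftr, which fell 4.46-fold. The metallothionein Mt2 rose 3.51-fold, the sialyltransferase St8sia6 3.28-fold, Tmem100 3.19-fold and the semaphorin receptor Plxna4 2.57-fold. In 1416 of the 1465 called genes all 4 mutant arrays lay on one side of all 4 controls. Of all genes, 12.6% did so, where chance gives 2.86%. The count of called genes ranged from 1020 to 1455 with 1 array left out and was 606 without the 3 arrays with raised Y-linked genes. The 1455 came without Dicer mutant 1, an array outside this comparison. Among the arrays compared, the highest count was 1376, without Yy1 mutant 2. Of the 13 lists that passed the test, 4 upwards and 9 downwards, 6 did so with an estimated correlation.

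**Figure D2:**
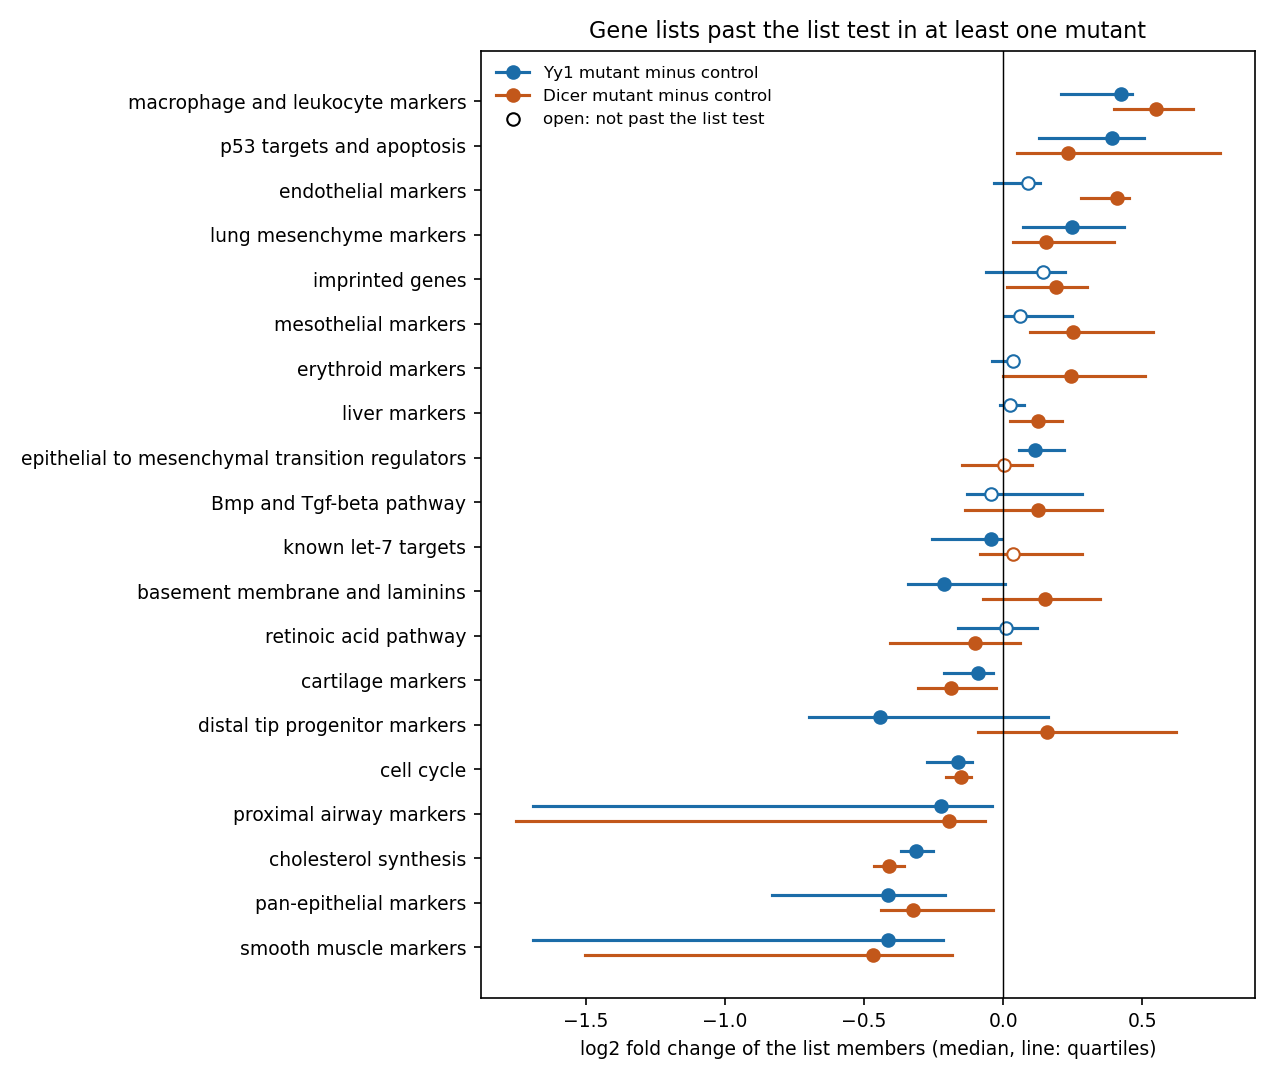
Median log2 fold change (circle) and quartiles (line) of the members of each gene list that passed the list test in at least 1 mutant, for Yy1 mutant and Dicer mutant lungs against the same 4 controls. Filled circles passed the test, and the distal tip list (-0.44 and 0.16) and the basement membrane list (-0.21 and 0.15) lay on opposite sides of 0 in the mutants.

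The comparison of Dicer mutant with control lungs concerns the gene that microRNA processing requires. MicroRNA processing itself was not measured. Dicer1 itself fell 1.53-fold. Macrophage, endothelial and mesenchymal markers and p53 targets were higher than in controls, and smooth muscle, proximal airway and cholesterol synthesis genes were lower. With an estimated correlation, the endothelial (adjusted p = 0.0996), mesenchymal (0.091), smooth muscle (0.0727) and cholesterol (0.0619) lists lost their calls. Hdc, which makes histamine, rose 12.4-fold from 5.63 ± 0.299 to 9.26 ± 0.655 (SD, n = 4; adjusted p = 3.63e-06), and Afp, the fetal serum protein alpha-fetoprotein, rose 6.84-fold from 6.07 ± 0.237 to 8.84 ± 0.625 (adjusted p = 1.03e-05). Aldh1a7 fell 20.2-fold from 10.31 ± 0.122 to 5.97 ± 0.340 and Sox2 fell 3.99-fold from 7.58 ± 0.208 to 5.59 ± 0.279. In all, 1940 genes were called, 1060 higher and 880 lower, of which 62 and 43 changed at least 2-fold.

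Of 25 pan-epithelial markers, 13 fell, 2 rose and 10 were not called. Adjusted over the list alone, 17 fell and 3 rose. The median was -0.32, with adjusted p = 1.41e-05 and adjusted p = 0.365 with an estimated correlation. Cldn6 fell by 0.81, the transcription factor Ehf by 0.76, the trafficking gene Rab25 by 0.80 and keratin 19 (Krt19) by 0.76. The protease inhibitor Spint1 rose by 0.67 and its target protease St14 by 0.41, both named after their values were seen. Nkx2-1 fell by 0.44 (adjusted p = 0.0344). That call was lost without control 1 (adjusted p = 0.0734), control 2 (0.0831), control 3 (0.0625), Dicer mutant 2 (0.106), Dicer mutant 3 (0.0525) or Dicer mutant 4 (0.0959), with 0.0778 without the 3 arrays with raised Y-linked genes. Of 13 proximal airway markers, 6 fell, also 6 adjusted over the list alone, with a median of -0.19, adjusted p = 4.86e-06 and adjusted p = 0.0161 with an estimated correlation. Beside Sox2, Aldh1a1 fell by 1.92 and Cckar by 1.55.

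Distal tip progenitor markers rose on balance. Of 14, 5 rose, 3 fell and 6 were not called, and 6 rose and 3 fell adjusted over the list alone (median 0.16, adjusted p = 0.00301, and adjusted p = 0.176 with an estimated correlation). Id2, an inhibitor of bHLH transcription factors, rose by 0.85 (SE 0.0782), from 10.24 ± 0.0653 to 11.09 ± 0.0579. Gata6 rose by 0.64, the laminin chain Lama1 by 0.76, Bmp4 by 0.73 and Spry2, an inhibitor of receptor tyrosine kinase signalling, by 0.56. Etv5 fell by 0.47, or by 0.25 when all its probe sets were averaged, and Sftpc by 1.14. Shh fell by 0.37 (adjusted p = 0.0251), a call lost without control 1 (adjusted p = 0.0754), control 2 (0.0589), Dicer mutant 2 (0.0772) or Dicer mutant 4 (0.0706), with 0.111 without the 3 arrays with raised Y-linked genes and 0.0601 in a fit of the 2 groups alone. Sox9 differed by 0.22 (adjusted p = 0.148). Fgfr2 differed by 0.01 (adjusted p = 0.976), and by -0.01 without control 1 or Dicer mutant 1 and -0.07 without Dicer mutant 4. Alveolar markers did not pass the list test (median 0.02, adjusted p = 0.0947), yet 7 of 16 rose and 3 fell (7 and 5 adjusted over the list alone). Surfactant protein B (Sftpb) rose 4.72-fold from 9.27 ± 0.377 to 11.51 ± 0.151, the surfactant lipid transporter Abca3 by 1.11 and Lamp3 by 1.44. Muc1 fell by 2.70.

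Smooth muscle markers fell, 9 of 13, also 9 adjusted over the list alone, with a median of -0.47, adjusted p = 1.66e-09 and adjusted p = 0.0727 with an estimated correlation. Myh11 fell 4.16-fold, the actin-binding gene Cnn1 4.04-fold, Myocd by 1.90 and Actg2 2.83-fold. Of 16 endothelial markers, 12 rose (13 adjusted over the list alone), with a median of 0.41, adjusted p = 1.58e-12 and adjusted p = 0.0996 with an estimated correlation. VE-cadherin (Cdh5) rose by 0.42, Emcn by 0.45, claudin 5 (Cldn5) by 0.48 and Sox17 by 0.41. Of 16 mesenchyme markers, 7 rose (8 adjusted over the list alone), with a median of 0.15, adjusted p = 2.3e-05 and adjusted p = 0.091 with an estimated correlation. Dcn rose by 0.88, Lum by 1.03, collagen gene Col1a1 by 0.40 and Fgf10 by 0.69. Of 16 macrophage and leukocyte markers, 12 rose (13 adjusted over the list alone), with a median of 0.55, adjusted p = 2.11e-14 and adjusted p = 0.0232 with an estimated correlation. C1qb rose by 0.95, Cd68 by 0.75, lysozyme (Lyz2) by 0.97 and Laptm5 by 0.66.

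Of 20 p53 targets and apoptosis genes, 9 rose (10 adjusted over the list alone), with a median of 0.23, adjusted p = 2.25e-11 and adjusted p = 0.0161 with an estimated correlation. Eda2r rose 3.48-fold, Ccng1 by 1.29, Cdkn1a 5.17-fold and Trp53inp1 1.99-fold. Of 10 cholesterol synthesis genes, 6 fell (8 adjusted over the list alone), with a median of -0.41, adjusted p = 1.01e-07 and adjusted p = 0.0619 with an estimated correlation. Sqle fell by 0.68, Insig1 by 0.49 and Dhcr7 by 0.39. Of 20 cell cycle genes, 4 fell (5 adjusted over the list alone), with a median of -0.15, adjusted p = 0.000107 and adjusted p = 0.187 with an estimated correlation. Mcm5 fell by 0.34 (adjusted p = 0.015, and 0.0849 without the 3 arrays with raised Y-linked genes).

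Of 19 basement membrane genes, 8 rose and 2 fell (9 and 2 adjusted over the list alone), with a median of 0.15, adjusted p = 0.00215 and adjusted p = 0.295 with an estimated correlation. Lama3 rose by 0.70 and Fras1, an extracellular matrix gene, by 0.57. Lamb3 fell by 0.59 and Frem1 by 0.26, named after their values were seen. Of 16 imprinted genes, 5 rose and 1 fell (7 and 2 adjusted over the list alone), with a median of 0.19, adjusted p = 0.00206 and adjusted p = 0.0996 with an estimated correlation. Zim1 rose by 0.81 and Igf2r by 0.37, while Nnat fell by 0.79, or by 0.50 when all its probe sets were averaged. Of 10 mesothelial markers, 4 rose (4 rose and 2 fell adjusted over the list alone), with a median of 0.25, adjusted p = 0.00301 and adjusted p = 0.135 with an estimated correlation, among them the mucin Muc16 by 0.61 and Gpm6a by 0.63. Of 18 Bmp and Tgf-beta genes, 5 rose and 2 fell (8 and 3 adjusted over the list alone), with a median of 0.13, adjusted p = 0.0173 and adjusted p = 0.199 with an estimated correlation. The inhibitory gene Smad6 rose by 0.43, and Tgfbi, an extracellular matrix gene induced by Tgf-beta, fell by 1.29.

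Of 9 erythroid markers, 2 rose (3 adjusted over the list alone), with a median of 0.24, adjusted p = 0.0086 and adjusted p = 0.176 with an estimated correlation. They were the anion exchanger Slc4a1, by 1.02, and the blood group gene Kel, by 0.51. Of 12 liver markers, Afp alone rose, also when adjusted over the list alone. The list gave a median of 0.12, adjusted p = 0.0209 and adjusted p = 0.413 with an estimated correlation, and its call was lost without control 2 (median 0.05, adjusted p = 0.0965) or Dicer mutant 1 (0.07 and 0.0884). Its median was 0.20 without Dicer mutant 2 and 0.06 without Dicer mutant 4. Of 14 cartilage markers, 2 fell (4 fell and 1 rose adjusted over the list alone), with a median of -0.19, adjusted p = 0.0263 and adjusted p = 0.206 with an estimated correlation. The call was lost without control 4 (adjusted p = 0.0608) or Dicer mutant 1 (0.0591), and the median was -0.12 without Dicer mutant 2. Cnmd fell by 0.98. Of 13 retinoic acid pathway genes, 4 fell (4 fell and 1 rose adjusted over the list alone), with a median of -0.10, adjusted p = 0.0293 and adjusted p = 0.283 with an estimated correlation. The call was lost without control 1 (adjusted p = 0.0507), Dicer mutant 1 (0.055) or Dicer mutant 3 (0.0529), and the median was -0.15 without control 2 and -0.17 without Dicer mutant 1. The receptor Rarb fell by 0.46 and the retinol transporter Stra6 by 0.75.

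Known let-7 targets did not pass the list test (median 0.04, adjusted p = 0.115), with 6 of 17 higher and 1 lower past the gene test (6 and 2 adjusted over the list alone). Hmga2, a chromatin protein gene of embryonic growth, rose by 0.57, Trim71 by 0.46 and Arid3a by 0.39, while cyclin D2 (Ccnd2) fell by 0.78. Among 13 microRNA biogenesis genes, the Argonaute partner Tnrc6a rose by 0.54 and Ago2 by 0.29, beside the fall of Dicer1 (3 rose and 1 fell adjusted over the list alone; list adjusted p = 0.512, median -0.000588, mean 0.01, test upwards). Of 14 Shh pathway genes, 3 fell and 1 rose (5 and 1 adjusted over the list alone; list adjusted p = 0.127, median -0.12). Ptch1 fell by 0.53 and Hhip by 0.75, and Gli1 differed by -0.19 (adjusted p = 0.105). Gli1 passed the test without control 2 (-0.25, adjusted p = 0.0305) and with array weights (-0.23, adjusted p = 0.0248). Of 17 Fgf pathway genes, 4 rose and 2 fell, the same counts adjusted over the list alone (list adjusted p = 0.115, median 0.09), and Fgfr3 fell by 0.72. Of 20 Wnt pathway genes, 1 rose and 4 fell (3 and 4 adjusted over the list alone; list adjusted p = 0.543, median -0.04). The Wnt inhibitor Dkk1 rose by 0.93, while Wnt11 fell by 0.60 and Wnt5a by 0.74.

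Among 15 stress response genes, 2 rose and 3 fell (3 and 4 adjusted over the list alone; list adjusted p = 0.934, median 0.04, mean -0.00373, test upwards), including Psat1, which fell by 0.42, and Dnajb9, which rose by 0.50. Among 13 hypoxia response genes, 1 rose and 2 fell (2 and 2 adjusted over the list alone; list adjusted p = 0.543, median 0.00567). Neuroendocrine markers (median -0.15, adjusted p = 0.295), Notch pathway genes (0.02, adjusted p = 0.22), neural markers (-0.03, adjusted p = 0.217), heart muscle markers (0.30, adjusted p = 0.406) and skeletal muscle markers (-0.11, adjusted p = 0.406) did not pass the test. The same held for oesophagus, stomach and thymus markers (-0.09, adjusted p = 0.125), oxidative phosphorylation (-0.07, adjusted p = 0.115), ribosomal proteins (-0.03, adjusted p = 0.764), regulators of epithelial to mesenchymal transition (0.00322, adjusted p = 0.468) and sex-linked genes (0.92, adjusted p = 0.406). Further large changes were those of the protease Ctse, which rose 5.19-fold, Habp2, a hyaluronan-binding protease, 4.83-fold, Prtg, an immunoglobulin superfamily receptor, 3.97-fold, and Fermt1, an integrin-binding kindlin, 3.78-fold. Cym fell 11.1-fold.

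In 1840 of the 1940 called genes all 4 Dicer mutant arrays lay on one side of all 4 controls. This held for 3538 of all genes, where chance gives 2.86% of them. The count of called genes ranged from 1275, without Dicer mutant 4, to 1991 with 1 array left out and was 976 without the 3 arrays with raised Y-linked genes. Of the 18 lists that passed the test, 11 upwards and 7 downwards, 3 did so with an estimated correlation.

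The mutants were compared with each other to find where the effects of the floxed Yy1 and Dicer alleles, with the same Cre allele, differ. The distal tip, basement membrane, endothelial and alveolar lists were lower in Yy1 mutants than in Dicer mutants. With an estimated correlation, the distal tip list alone kept its call, and the basement membrane (adjusted p = 0.0727), endothelial (0.171) and alveolar (0.192) lists lost theirs. Fermt1 was 5.63-fold lower in Yy1 mutants (6.14 ± 0.0766 against 8.64 ± 0.180; SD, n = 4; adjusted p = 4.86e-08), Hdc 8.46-fold lower and Adamts18, a secreted metalloprotease, 6.09-fold lower. Of the 1101 genes called, 348 were higher and 753 lower in Yy1 mutants, 5 and 60 of them at least 2-fold. The count fell to 726 without Dicer mutant 4 and ranged up to 1180 with 1 array left out, and it was 435 without the 3 arrays with raised Y-linked genes. The 1180 came without control 2, an array outside this comparison. Among the arrays compared, the highest count was 1026, without Yy1 mutant 2. In 1070 of the called genes the arrays of the mutants did not overlap. Of all genes, 13.8% did not, where chance gives 2.86%.

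Of 14 distal tip markers, 11 were lower and 1 higher in Yy1 than in Dicer mutants (12 and 1 adjusted over the list alone), with a median of -0.62, adjusted p = 1.95e-16 and adjusted p = 0.00886 with an estimated correlation. It was the 1 list of the 15 called that also passed with an estimated correlation. Id2 differed by -0.75, Fgfr2 by -0.85, Wnt7b by -0.68, Foxp2 by -0.81 and Sox9 by -0.65. Etv4, named after its value was seen, was 0.40 higher. Of 19 basement membrane genes, 8 were lower (11 adjusted over the list alone), with a median of -0.21, adjusted p = 7.77e-14 and adjusted p = 0.0727 with an estimated correlation. Lama3 differed by -1.74, Fras1 by -0.83 and Frem2 by -0.46. Of 16 endothelial markers, 8 were lower (13 adjusted over the list alone), with a median of -0.32, adjusted p = 1.14e-12 and adjusted p = 0.171 with an estimated correlation. The Vegf receptor Kdr differed by -0.39 and Sox17 by -0.37. Of 16 alveolar markers, 5 were lower (7 lower and 1 higher adjusted over the list alone), with a median of -0.32, adjusted p = 1.37e-06 and adjusted p = 0.192 with an estimated correlation. Abca3 differed by -1.29, Sftpb by -1.30 and Sftpc by -1.24.

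Of 25 pan-epithelial markers, 12 were lower and 3 higher in Yy1 mutants (14 and 5 adjusted over the list alone), with a median of -0.33, adjusted p = 8.23e-06 and adjusted p = 0.422 with an estimated correlation. The cell adhesion gene Epcam differed by -0.57, Spint1 by -0.88 and the protease Prss8 by -0.79. The 3 that were higher, Rab25 by 0.75, Krt18 by 0.31 and Ehf by 0.41, were named in part after their values were seen, and without the 3 arrays with raised Y-linked genes Rab25 had adjusted p = 0.122. Of 17 let-7 targets, 7 were lower and 1 higher (8 and 2 adjusted over the list alone), with a median of -0.18, adjusted p = 3.21e-05 and adjusted p = 0.0845 with an estimated correlation. Hmga2 differed by -0.84 and Ccnd2 by 0.50. Of 18 Bmp and Tgf-beta genes, 5 were lower and 2 higher (7 and 2 adjusted over the list alone), with a median of -0.13, adjusted p = 0.00258 and adjusted p = 0.171 with an estimated correlation. Bmp4 differed by -0.43 and Tgfbi by 1.15, and the median was -0.08 without Yy1 mutant 4 or Dicer mutant 1. Of 17 Notch pathway genes, 2 were lower (3 adjusted over the list alone), with a median of -0.13, adjusted p = 0.00247 and adjusted p = 0.279 with an estimated correlation. Notch2 differed by -0.29 (adjusted p = 0.00861, and 0.195 without the 3 arrays with raised Y-linked genes).

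The remaining list differences past the list test had adjusted p-values of 0.0121 or more. Macrophage markers were lower in Yy1 mutants (median -0.12, adjusted p = 0.0121, and adjusted p = 0.395 with an estimated correlation), with 1 of 16 past the gene test and 2 adjusted over the list alone. Erythroid markers were lower (median -0.12, adjusted p = 0.0121, adjusted p = 0.237 with an estimated correlation, 0.0787 without Yy1 mutant 2, 0.0712 without the 3 arrays with raised Y-linked genes and 0.083 without the dimmest genes), with Slc4a1 and Kel at -1.06 and -0.58 (2 of 9, and 3 adjusted over the list alone). The median was -0.20 without Yy1 mutant 4, -0.07 without Dicer mutant 1 and -0.19 without Dicer mutant 4. MicroRNA biogenesis genes were lower (median -0.13, adjusted p = 0.0166, adjusted p = 0.171 with an estimated correlation and 0.0896 after quantile normalisation), with 2 lower and 1 higher of 13 (6 and 1 adjusted over the list alone). Dicer1 itself differed by 0.47 (adjusted p = 0.0101) and Tnrc6a by -0.49 (adjusted p = 0.00503), and without the 3 arrays with raised Y-linked genes their adjusted p was 0.0536 and 0.0846. Retinoic acid genes were higher (median 0.15, adjusted p = 0.0266, and adjusted p = 0.316 with an estimated correlation), where 3 of 13 passed adjusted over the list alone. That call was lost without Yy1 mutant 1 (median 0.10, adjusted p = 0.111) or Yy1 mutant 3 (0.0532). Fgf pathway genes were lower (median -0.07, adjusted p = 0.0433, and adjusted p = 0.316 with an estimated correlation), with 4 lower and 2 higher of 17 (4 and 3 adjusted over the list alone). The call was lost without control 1 (adjusted p = 0.0548), Yy1 mutant 3 (0.0532), Yy1 mutant 4 (0.0756), Dicer mutant 1 (0.0668) or Dicer mutant 2 (0.066), and the median was -0.12 without Yy1 mutant 1 or Dicer mutant 3.

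Ribosomal protein genes were higher in Yy1 mutants (median 0.08, adjusted p = 0.0433, and adjusted p = 0.586 with an estimated correlation), with 1 of 20 past the gene test and also 1 adjusted over the list alone. That call was lost without control 1 (adjusted p = 0.0511), control 4 (0.0509), Yy1 mutant 1 (0.112), Yy1 mutant 3 (0.0708), Yy1 mutant 4 (0.206), Dicer mutant 1 (0.0884), Dicer mutant 3 (0.0669) or Dicer mutant 4 (0.0589), and the median was 0.12 without Yy1 mutant 2 and 0.05 without Yy1 mutant 4. Oesophagus, stomach and thymus markers were higher (median 0.18, adjusted p = 0.0433, and adjusted p = 0.519 with an estimated correlation), where 1 of 13 passed adjusted over the list alone. This call was lost without control 1 (adjusted p = 0.0511), Yy1 mutant 2 (0.0862), Yy1 mutant 3 (0.0532), Yy1 mutant 4 (0.06), Dicer mutant 2 (median 0.12, adjusted p = 0.216) or Dicer mutant 3 (0.056).

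The smooth muscle list (median -0.02, adjusted p = 0.488), the proximal airway list (-0.00903, adjusted p = 0.849), the mesenchyme list (0.03, adjusted p = 0.65), the cholesterol list (0.07, adjusted p = 0.753), the cell cycle list (-0.02, adjusted p = 0.465) and the p53 list (0.08, mean -0.03, test downwards, adjusted p = 0.56) did not differ past the test between the mutants. Other lists that did not were those for the Shh pathway (0.12, adjusted p = 0.271), epithelial to mesenchymal transition (0.16, adjusted p = 0.091), liver (-0.06, adjusted p = 0.0991), neuroendocrine cells (0.11, adjusted p = 0.585), neural cells (0.13, adjusted p = 0.163), heart muscle (-0.17, adjusted p = 0.465) and cartilage (0.04, adjusted p = 0.849). The lists for oxidative phosphorylation (0.02, adjusted p = 0.465), the stress response (-0.00608, adjusted p = 0.465) and sex-linked genes (0.43, adjusted p = 0.979) did not either. In the imprinted list 4 of 16 genes were lower (4 lower and 1 higher adjusted over the list alone; median -0.03, adjusted p = 0.0685), and in the mesothelial list 3 of 10 were lower and 1 higher (4 and 1 adjusted over the list alone; median -0.03, adjusted p = 0.151). Of 20 Wnt pathway genes, 3 were lower and 3 higher (4 and 4 adjusted over the list alone; median -0.03, adjusted p = 0.446), with Wnt7b lower and the Wnt agonist Rspo2 0.53 higher. Median and mean had opposite signs for skeletal muscle markers (-0.02 and 0.01, test downwards, adjusted p = 0.922) and hypoxia response genes (0.05 and -0.00826, test upwards, adjusted p = 0.877). Hhip was the Shh pathway gene that differed most, by -1.20. Among genes higher in Yy1 mutants, the homeobox gene Meox1 was 2.49-fold higher and Fgf20 2.37-fold.

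Many genes changed alike in the mutants. Of the 736 genes called in both against the shared controls, 704 (95.7%) changed in the same direction, 326 higher and 378 lower, and independent lists of these sizes would share 29.3 and 33.8. Those called in both made up 50.2% of the Yy1 calls and 37.9% of the Dicer calls. Cdkn1a, Mt2 (3.51-fold and 3.37-fold), St8sia6 (3.28-fold and 3.98-fold) and Lum rose in both. Aldh1a7, Muc1, Cym, Myh11 and Sox2 fell in both. Because the mutants share 4 controls, some likeness is built in. In 100 simulations of unchanged groups, 0 genes were called in both mutants in either direction. The mean correlation of the simulated effects across genes was 0.451 (from -0.533 to 0.926), so the observed 0.602 lies inside their range. The simulated effects varied less across genes, with mean variances of 0.0128 and 0.0136 in Yy1 and Dicer mutants against 0.0444 and 0.0499 observed. Their range of correlations is therefore a limited yardstick for these data. The covariance was 0.0283, which is 0.0217 above the mean of the simulations (0.00663) and just above their highest value, 0.0282. With different controls for each mutant, 125 genes were higher in both and 165 lower in both on average, the correlation was 0.382 (from 0.262 to 0.441) and the covariance was 0.0207. Genes are not independent replicates, so these correlations carry no p-value. The shared count was 497 to 660 with 1 array left out and 256 without the 3 arrays with raised Y-linked genes.

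The other 32 genes called in both changed in opposite directions, where independent lists would give 65.0 and different controls for each mutant gave 19.7 on average (from 9 to 50), and most of them fell in Yy1 mutants and rose in Dicer mutants. Adamts18 fell by 1.53 in Yy1 mutants and rose by 1.07 in Dicer mutants, and Fermt1 fell by 0.58 and rose by 1.92. Lama3 fell by 1.04 and rose by 0.70. Further genes, chosen after their values were seen, were the carboxypeptidase Cpm, which fell by 0.85 and rose by 0.92, the ephrin receptor Epha4, which fell by 0.74 and rose by 0.86, complement factor I (Cfi), which fell by 0.66 and rose by 1.17, and Cpn1, which fell by 1.03 and rose by 0.76. Id4 rose by 0.46 in Yy1 mutants and fell by 0.46 in Dicer mutants.

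**Figure D3:**
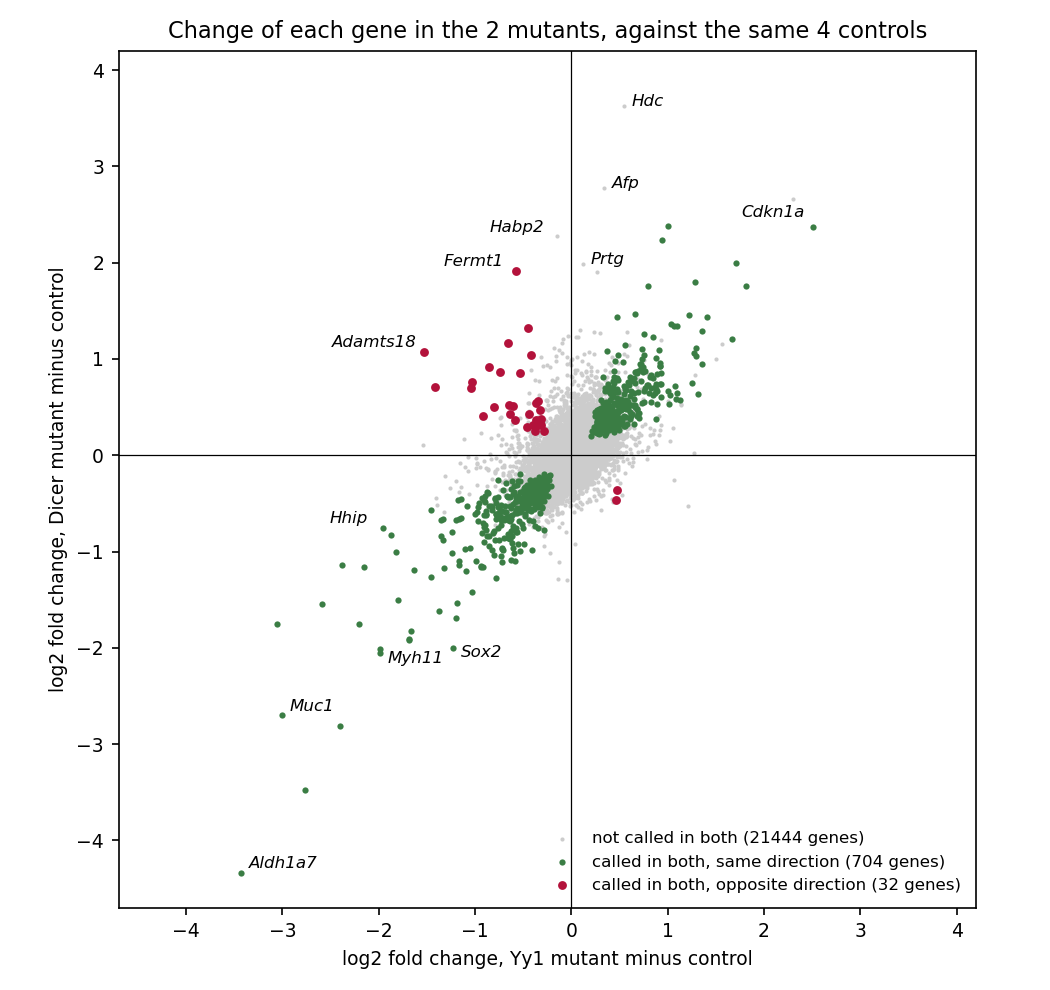
Log2 fold change of each of 22180 genes in Yy1 mutant lungs (horizontal axis) and Dicer mutant lungs (vertical axis) against the same 4 controls, with 1 point per gene. Green points are the 704 genes called in both mutants in the same direction and red points the 32 called in opposite directions.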

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

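The tests of liver carry-over, of a lower epithelial share and of single male embryos, and the covariate of Xist minus Eif2s3y, were chosen only after the results were seen. Chance as the reason for the number of called genes is argued against by splits of the 8 arrays, though not excluded. Of 35 splits in each comparison, only 1, the real one, gave as many genes as were called. With 35 splits, no smaller share than 1 of 35 is possible. The other splits mix the genotypes, which widens their spread and lowers their counts. The real counts were 1465, 1940 and 1101, and the highest counts of the other splits were 1, 0 and 0 (limma, with 4266, 4948 and 3965 genes at an unadjusted p under 0.05 in the real splits).

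In Yy1 mutant lungs 15 of 25 epithelial markers fell and 10 were not called (median -0.42), and the list test was not passed with an estimated correlation (adjusted p = 0.13). A lower share of epithelial cells alone would raise the markers of all other cell types alike, but the smooth muscle markers had a median of -0.41 while mesenchyme and macrophage markers rose. A scaling shift left in the values used here, which would move all genes alike, is argued against by the median of all genes, 0.00161. The list also kept its call after equal array medians. The list test sets a list against all other genes, so a shift of all genes alike largely cancels in it. The kept call therefore does not bear on a scaling shift. The values had been normalised between arrays, so the median of all genes cannot show a shift from before that step. A lower epithelial share together with a loss of smooth muscle transcripts remains open, as does a lower level per epithelial cell. Whole lung RNA does not separate these.

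On 3 mutant arrays the Y-linked genes stood above the other arrays, with Eif2s3y, Kdm5d and Uty at 7.99, 7.62 and 8.52 in Yy1 mutant 2, 7.84, 7.70 and 8.28 in Dicer mutant 4 and 5.92, 4.70 and 5.14 in Yy1 mutant 3, where Xist read 8.55, 9.64 and 11.11 and the controls 11.15 to 11.31. A single male embryo as the specimen of Yy1 mutant 3 is argued against by Xist, which differed from the mean of the controls by -0.12, while for Yy1 mutant 2 and Dicer mutant 4 it cannot be told apart from RNA of both sexes, since Xist differed by 1.09 between them and no array known to be male gives its background. RNA of embryos of both sexes in 1 specimen is a candidate explanation that the labels neither give nor exclude. Sex content as the whole source of the calls is argued against by the share of called genes that stayed called with Xist minus Eif2s3y as covariate, 0.713 in the Yy1 mutant and 0.808 in the Dicer mutant, although without the 3 arrays 563 of 1465 and 960 of 1940 stayed called, with fewer arrays. No control array had raised Y-linked genes, so a part of the calls that follows sex content remains open.

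Afp rose by 2.77 in Dicer mutant lungs. Liver tissue carried over at dissection would bring its other abundant transcripts, but the other liver markers had a median of 0.10, with Apoa2 at -0.02 (6.83 in controls and 6.81 in mutants) and Apoa1 at 0.21. Alb differed by 0.82 (adjusted p = 0.147), from 5.62 to 6.44, with an SD of 0.937 among the Dicer mutants, and by 1.11 without Dicer mutant 3 (adjusted p = 0.0414, and 0.0414 to 0.262 over the alternatives). Erythroid markers, which fetal liver also expresses, go the way of a carry-over (median 0.24, adjusted p = 0.0086, and adjusted p = 0.176 with an estimated correlation). Expression of Afp by cells of the mutant lung remains open as a biological explanation and was not tested.

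Among 198 named and sex-linked genes, each in 3 groups, 41 of 594 sets of 4 arrays held 1 array far from the other 3. Chance alone gives about 1 in 20, or 29.7. These were 13 sets in controls, 12 in Yy1 mutants and 16 in Dicer mutants. In control 1, Ccng1 (9.20), Wnt7b (7.95), Ctse (7.65) and Hmgcs1 (10.13) were high and Dkk1 (5.61) and Hey2 (7.25) low. In control 2, Mmp2 (10.77), Sftpb (9.84), Lama4 (10.21) and Prss8 (9.32) were high and Gli1 (7.66) and Kel (5.39) low. In control 3, Aldh1a7 was high (10.49). In Yy1 mutant 1, Tinag (5.45), Fras1 (8.66) and Foxp2 (9.20) were high. In Yy1 mutant 2, Pdpn (8.29), Meox1 (8.59) and Nrarp (7.67) were high and Id2 (10.11), Mcm2 (9.16), Hbb-y (11.06) and Xist (8.55) low. Epb42 was low in Yy1 mutant 3 (6.24) and Kel high in Yy1 mutant 4 (5.66). In Dicer mutant 1, Sgce was low (8.38). In Dicer mutant 2, Laptm5 (6.92) and Gata6 (10.17) were high and Lyz2 (7.23) and Zim1 (9.40) low. In Dicer mutant 3, Pdpn (8.57), Bub1b (8.78), Ctse (9.98) and Rhag (5.90) were high and Rpl10a (9.93) low. In Dicer mutant 4, Ccng1 (10.54), Eif2s3y (7.84), Kdm5d (7.70) and Uty (8.28) were high and Fgfr1 (8.14) and Xist (9.64) low.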

How the results depend on the processing

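The covariate of Xist minus Eif2s3y and the removal of the 3 arrays with raised Y-linked genes were chosen only after the results were seen. A planned covariate of Xist minus Ddx3y was not run, because the annotation lists no probe set for Ddx3y alone, and a pseudocount does not apply to log2 values. With 1 array left out, 1020 to 1455 genes were called in the Yy1 mutant, against 1465. In the Dicer mutant 1275 (without Dicer mutant 4) to 1991 were called, against 1940. Between the mutants 726 (without Dicer mutant 4) to 1180 were called, against 1101. The 1455 and the 1180 came without Dicer mutant 1 and control 2, arrays outside those comparisons. Shared calls ranged from 497 to 660 against 704, the correlation of the effects from 0.576 to 0.633, and the number of shifted lists from 11 to 15, 16 to 19 and 11 to 15. Removing the 3 arrays left 606, 976 and 435 called genes and 256 shared calls, and 563, 960 and 407 of those genes were among the original calls. This alternative has fewer arrays, and how much of the loss is due to that was not tested. A minimum change of 1.5-fold left 391, 450 and 300 genes and 182 shared calls, by construction. Array weights gave 1804 genes in the Yy1 mutant, 2800 in the Dicer mutant and 1806 between the mutants, with 902 shared calls, and the cause was not tested. With each mutant set against its own pair of controls, shared calls averaged 289.5 and the correlation 0.382, with 2 of the 4 controls in each comparison. With the correlation estimated from the data, 6, 3 and 1 lists passed instead of 13, 18 and 15. The estimate was 0.526 for the pan-epithelial, 0.494 for the endothelial and 0.278 for the smooth muscle list, against the preset 0.01. A higher correlation makes the list test harder to pass, and so do the 9 residual degrees of freedom that camera uses with an estimate. The proximal airway list, with an estimate of 0.00317, went from adjusted p = 2.9e-07 to 0.01 in the Yy1 mutant. That estimate is below the preset, so a higher correlation cannot account for its change. A call lost with an estimated correlation is therefore not the effect of correlation alone. The share of each was not tested.

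Equal array medians gave 1406, 1793 and 1053 genes and quantile normalisation 1681, 2241 and 1232. Without the dimmest 30% of genes, where fewer genes are tested, 1838, 2374 and 1387 were called. The mean of all probe sets gave 1410, 1871 and 1062, the intensity trend with a robust prior 1893, 2461 and 1443, the fit of only the groups compared 1112, 1514 and 1029, and the covariate of Xist minus Eif2s3y 1119, 1613 and 1004. The replicate block gave 1301, 1848 and 997 genes. Whether the replicate numbers pair the arrays is not given by the labels. Of 12 same-number pairs, 3 correlated above 0.1 (from -0.161 to 0.19). Of the 12 arrays, 0 correlated best with their own number in both other groups. These values show no pairing by number, and they do not exclude it. The cartilage call in the Yy1 mutant was lost with the replicate block (adjusted p = 0.0509) and with the covariate (0.0722), which also ended the call of the oesophagus, stomach and thymus list between the mutants (0.0589), and the mean of all probe sets ended that of the Fgf list there (0.067). Over all alternatives the lists that had passed their test kept direction and call in 874 results and lost the call in 92. Lists that had not passed were not followed one by one, and calls gained among them are not in these numbers: without control 1, for example, 15 lists passed in the Yy1 mutant. Removing the 3 arrays left 14, 17 and 13 lists past the test, with calls lost for the cartilage (adjusted p = 0.118) and let-7 (0.0774) lists in the Yy1 mutant, the liver list (0.0539) in the Dicer mutant, and the erythroid (0.0712) and oesophagus, stomach and thymus (0.0995) lists between the mutants. Among the scaling alternatives, the calls lost were between the mutants, for the Fgf pathway (adjusted p = 0.169), oesophagus, stomach and thymus (0.113) and microRNA biogenesis (0.0896) lists after quantile normalisation and for the ribosomal list (0.0565) after equal array medians. Without the dimmest genes, the cartilage list was lost in the Yy1 mutant (adjusted p = 0.146), the Bmp (0.0504), retinoic acid (0.0648), cartilage (0.096), erythroid (0.0648) and liver (0.074) lists in the Dicer mutant, and the Fgf (0.101) and erythroid (0.083) lists between the mutants. The named genes include genes that were not called. Their direction and status, called or not called, stayed the same in 6123 results. They lost the call in 290, gained it in 84 and changed direction in 8.

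Those 8 were differences near 0 that did not pass the test. Gli1 in the Yy1 mutant was -0.03 and became 0.000640 with the covariate of Xist minus Eif2s3y and 0.00236 without Yy1 mutant 2 (-0.0794 to 0.00236 with 1 array left out). Fgfr2 in the Dicer mutant was 0.01 and became -0.0462 with that covariate, -0.0658 without the 3 arrays, -0.0143 without control 1, -0.0126 without Dicer mutant 1 and -0.0658 without Dicer mutant 4 (-0.0658 to 0.10 with 1 array left out). Yy1 in the Dicer mutant was -0.03 and became 0.00505 without control 2 (-0.0543 to 0.00505 with 1 array left out). The cause was not tested. Signal over background limits genes near the low end of the scale. The median level of the microRNA genes was 5.17, against array medians of 5.99 to 6.08.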

Other observations

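The tests in this part other than that of all microRNA genes with the preset correlation were chosen only after the results were seen, and the genes named were chosen after their values were seen. Some genes of microRNAs that lie between Dlk1 and Dio3, an imprinted cluster, rose in both mutants. Of 43 such genes, which were not tested as a list, 14 rose in Yy1 mutants and 13 in Dicer mutants, with medians of 0.40 and 0.33, and 41 and 40 of them lay above 0. Of the other 435 microRNA genes, 5 rose and 6 fell in Yy1 mutants and 9 rose and 1 fell in Dicer mutants, with medians of 0.03 and 0.01. After quantile normalisation the medians of the cluster were 0.41 and 0.31, and after equal array medians 0.39 and 0.33. Mir341 rose by 0.61 and 0.37 and Mir300 by 0.79 and 0.73 in Yy1 and Dicer mutants. Rian, a long noncoding RNA of the cluster, rose by 0.58 (adjusted p = 0.000638) and 0.56 (adjusted p = 0.000767), while Dlk1 rose in Dicer mutants by 0.32 (adjusted p = 0.0242) and differed by 0.16 in Yy1 mutants (adjusted p = 0.294). Meg3 (0.15, adjusted p = 0.443, and 0.20, adjusted p = 0.257) and Dio3 (-0.22, adjusted p = 0.46, and -0.12, adjusted p = 0.697) were not called in Yy1 or Dicer mutants. Genes of this cluster share transcripts, so they are not independent.

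Among 318 families of genes with a common symbol stem, the Pcdhb family of clustered protocadherins, cell adhesion molecules of neurons, was higher in Yy1 mutants. Of 22 genes, 8 rose, with a median of 0.39 (adjusted p = 1.23e-08, and adjusted p = 0.979 with an estimated correlation), and 8 rose after quantile normalisation and after equal array medians as well. Pcdhb12 rose by 0.79. In Dicer mutants the family had a median of 0.09 (adjusted p = 0.109), and between the mutants it was higher in Yy1 mutants by a median of 0.24 (adjusted p = 0.00155, and adjusted p = 0.96 with an estimated correlation). Of 10 Hoxb homeobox genes, 3 rose in Yy1 mutants (3 after quantile normalisation and 2 after equal array medians), with a median of 0.20 (adjusted p = 0.0276, and adjusted p = 0.979 with an estimated correlation). Adamts metalloproteases were higher in both mutants. Of 18, 8 rose and 1 fell in Dicer mutants (median 0.32, adjusted p = 1.77e-05, and adjusted p = 0.279 with an estimated correlation), and 7 rose and 1 fell in Yy1 mutants (median 0.20, adjusted p = 0.000775, and adjusted p = 0.979 with an estimated correlation).

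A build-up of unprocessed precursors without Dicer was tested as a hypothesis on all 478 microRNA genes. Their median in Dicer mutants was 0.0225, with 22 risen and 1 fallen. The median lay within the bound set for no build-up. The list test, whose passing was the sign set for a build-up, was passed with the preset correlation, so the signs set beforehand conflict. The median level of these genes was 5.17. Mir154, at 4.91 in controls, and Mir379, at 4.04, were called risen in Dicer mutants, so a low level alone does not hide every rise. Both lie in the cluster and were also called risen in Yy1 mutants, by 0.60 and 0.66. Their rise is therefore not particular to Dicer mutants. camera gave adjusted p = 0.0136 over the 3 comparisons, adjusted p = 0.0977 with an estimated correlation, and adjusted p = 0.201 for the 435 genes outside the cluster. The cluster held 13 of the 22 that rose. Yy1 mutants, whose Dicer alleles were not floxed, gave adjusted p = 0.0136, adjusted p = 0.0977 with an estimated correlation and adjusted p = 0.201 outside the cluster (19 risen and 6 fallen in all), and the mutants did not differ past the test (adjusted p = 0.981). These values neither show nor exclude a build-up. Whether the probe sets detect unprocessed precursors was not tested.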
